A study of Homo sapiens with 6 samples.

How the data were processed

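The deposited table held 29323 genes by 6 libraries, 3 of TF-1 cells with wild-type IDH and 3 of TF-1 cells with the IDH2 R140Q mutation, and each library was matched to its group by the library number in the labels. Per the submitters' processing notes, STAR 2.5, HTSeq 0.6.1 and DESeq2 version 2 were used, without a statement of settings, strand, annotation or genome build. Per the file headers, the authors deposited raw read counts per gene and library, and these whole numbers were the input here. Per the file headers, the FPKM values were also deposited by the authors, and they equal the counts divided by gene length and by the library's total. The authors also deposited a signal value per group, which equals the mean over 3 libraries of counts divided by median-of-ratios size factors. The log2 fold changes deposited by the authors are mutant over WT and were pulled toward 0 for low counts. Regressed on the log2 ratio of the deposited group means, they had a slope of 0.910 for genes with a mean count above 500 and of 0.520 for a mean count of 5 to 50. The p-value and adjusted p of the authors' own comparison were deposited too, and were used here only for the comparison of calls.

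Of the gene identifiers, 27817 were matched to symbols, and older symbols are given as the deposited table or the fixed lists use them. Positions are those of the deposited table, whose genome build is not named in the sources used here. It is not that of GENCODE 29 (GRCh38), since only 169 of 27975 shared identifiers lay at the same position. GC content, transcript length and 3′ UTR sequences were taken from GENCODE 29 by gene identifier. Of the tested genes, 55.6% overlap another gene, and whether counting used strand is not stated.

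The lists of genes, the tests, the rule for named genes and the alternatives, other than those named below as added, were fixed before the data were examined. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15389. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, 2-sided. The common biological coefficient of variation was 16.1%. Of the tested genes, 4604 had an unadjusted p below 0.05. Standard errors are those of the edgeR coefficient as derived from its F statistic. Of all tested genes, 36.1% had no overlap between the 3 WT and the 3 mutant values, against 10% by chance.

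The 29 lists, with 930 of 975 genes present in the table, covered IDH and TCA cycle enzymes, methylation regulators, blood lineages, metabolism, stress, proliferation, survival, immune genes, adhesion, cancer-testis genes and markers of cells foreign to the culture. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the estimated correlation and with fry as alternatives. Chromosomes were tested with camera at the preset correlation too, and with the estimated correlation, library size alone, the GC trend removed and each library left out as alternatives, but not with fry.

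Named genes were IDH2 and IDH1, then the 12 largest rises and 12 largest falls among protein-coding genes that passed, changed at least 2-fold, had a mean CPM of at least 5 and showed no overlap between groups. From each list the rule took the 2 largest rises and the 2 largest falls among members that passed with a mean CPM of at least 1, or the 2 highest members where none passed. A few genes that the rule takes are not reported here. Genes named outside this rule, such as single list members without an SE, HM13 and the genes around let-7, were chosen after their values were seen.

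Alternatives were RLE and upper-quartile factors, library size alone, no filter, a filter at a CPM of at least 1 in 3 libraries, counts thinned to the smallest library, protein-coding genes only, DESeq2 1.42.0, limma-voom, an adjusted p below 0.01, and each library left out in turn. Removal of each library's GC trend (lowess, span 0.3) and leaving out chromosome 20 were added after the data were seen. With 3 against 3 libraries the smallest p of an exact permutation test is 0.1, so no single gene was tested that way.

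In a self-test, counts for 15389 genes were simulated with 200 changed genes. At the threshold edgeR recovered 10% of those changed 1.5-fold, 60% at 2-fold, 94% at 4-fold and 100% at 8-fold. It made 18 false calls among 150, a share above the 0.05 of the threshold. The data gave 2188 calls, and with fewer changed genes the adjustment is stricter, so the shares recovered do not carry over to the data. With no change simulated edgeR made 0 calls, DESeq2 and limma-voom being run only on the changed set. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables, 3′ UTR sites and plots.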

Results

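Gene expression was measured by RNA sequencing of total RNA from TF-1 cells, a human erythroleukemia line that depends on cytokines such as GM-CSF for growth. The line with wild-type IDH (WT) was set beside an isogenic TF-1 line that carries the R140Q mutation of IDH2, the mitochondrial isocitrate dehydrogenase. Substitutions at this residue, recurrent in acute myeloid leukemia, let the enzyme make 2-hydroxyglutarate. Each group held 3 libraries. The mutant libraries were labelled as controls of day 28 and the WT libraries as controls without a day, so mutation and time in culture could not be separated. The labels do not say whether libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Gene counts summed to 17623233, 14453491 and 15934114 in WT replicates 1 to 3 and to 18862371, 17629135 and 14701814 in mutant replicates 1 to 3. Of 29323 genes in the table, 15389 passed the filter on low counts and were tested. The first principal component carried 57.6% of the variance and separated the groups. The second set WT replicate 1 apart from the other WT libraries. Relative to the mean of all libraries, log2 CPM in WT replicate 1 rose by 0.27 per 10% of GC content. In the other libraries this slope lay between -0.13 and 0.06. Levels below are TMM-scaled CPM, given as mean ± SD over 3 libraries. Fold changes are given as log2 of mutant over WT ± SE.

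The comparison asked which transcripts differ between IDH2-mutant and WT TF-1 cells. In the mutant line, genes of antigen presentation and inflammatory genes were higher. The oncofetal RNA-binding proteins LIN28B, IGF2BP1 and IGF2BP2 and the embryonic, fetal and alpha globins were lower, while the adult globin HBB was higher. HLA-B, for example, had a log2 fold change of 3.80 ± 0.22 and LIN28B one of -5.91 ± 0.21 (n = 3 per group). The inflammatory list's call held with an estimated correlation (adjusted p = 0.0461) and that of antigen presentation did not (adjusted p = 0.352 with an estimated correlation). Nor did that of the erythroid list (camera adjusted p = 0.816 with an estimated correlation). IDH2 itself fell 1.79-fold, from 105 ± 18.0 to 58.3 ± 3.63 CPM (log2 fold change -0.84 ± 0.13, edgeR adjusted p = 0.00411), and was lower in each mutant library than in any WT library. Its cytosolic relative IDH1 showed a log2 fold change of 0.04 ± 0.13 (edgeR adjusted p = 0.882), with levels of 58.8 ± 3.02 to 60.3 ± 10.3 CPM, and lay on the other side of 0 without mutant replicate 1 (-0.11) or with the GC trend of each library removed (-0.09). IDH2 (ENSG00000182054) lies on chromosome 15 from 90626277 to 90645736 in the coordinates of the deposited table, whose genome build is not named and is not GRCh38.

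In all, 2188 of the 15389 tested genes changed at an edgeR adjusted p below 0.05. Of these, 1163 were higher and 1025 lower in the mutant line, and 930 changed at least 2-fold. The authors' deposited table called 1220 genes higher and 1220 lower at an adjusted p below 0.05, and 2069 of its calls were also called here, all in the same direction. The count depended on single libraries. It was 3814 without WT replicate 1, 1360 without WT replicate 2, 2775 without WT replicate 3, and 897, 1100 and 1007 without mutant replicates 1, 2 and 3. No gene called with all libraries changed sign in any of these fits. Without a filter on low counts 3441 genes passed, and at an adjusted p below 0.01 the count was 901. With the GC trend of each library removed 2501 genes passed, of which 1885 were among the 2188. With library size alone in place of TMM factors, 60.4% of the calls were higher in the mutant line, against 53.2% with them. That share was 46.8% without a filter and 43.7% without WT replicate 3, where 1213 genes were higher and 1562 lower.

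Among well expressed protein-coding genes, the largest rise was that of CREB5, a CREB-family transcription factor, from 0.481 ± 0.202 to 12.2 ± 0.483 CPM (log2 fold change 4.63 ± 0.26, edgeR adjusted p = 3.77e-05). HLA-DQA1, a class II antigen-presenting chain, rose 16.8-fold (4.07 ± 0.29), and the class I chain HLA-B rose from 10.7 ± 2.98 to 149 ± 27.2 CPM (3.80 ± 0.22). The coagulation genes F13A1 and F5 rose by 3.75 ± 0.20 and 3.46 ± 0.19. SCN9A, a sodium channel, rose by 3.94 ± 0.26 and TEX19, a germ cell gene, by 3.56 ± 0.20. Other large rises were those of MB21D2 (3.58 ± 0.20), HSH2D (3.31 ± 0.21), the ephrin receptor EPHA7 (3.19 ± 0.20) and LRRN3 (3.17 ± 0.21). For the genes named here the edgeR adjusted p was 1.00e-04 or lower.

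Under the same limits on type and level, the falls of LIN28B, TMPRSS15 and IGF2BP2 were the largest and lay within error of each other. LIN28B, an RNA-binding protein that blocks maturation of let-7 microRNAs, dropped from 63.1 ± 9.99 to 1.06 ± 0.280 CPM (log2 fold change -5.91 ± 0.21, edgeR adjusted p = 4.94e-06). The mRNA-binding proteins IGF2BP1 and IGF2BP2, which like LIN28B are most active in fetal tissue, fell from 199.5 ± 25.8 to 9.84 ± 1.36 CPM (-4.34 ± 0.16) and from 20.4 ± 5.21 to 0.379 ± 0.238 CPM (-5.76 ± 0.39). EDNRB, an endothelin receptor, fell 30.6-fold (-4.93 ± 0.31), DMXL2 27.9-fold (-4.80 ± 0.32) and the integrin chain ITGB5 by the log2 value -4.32 ± 0.37. TMPRSS15, which encodes enteropeptidase, fell from 11.2 ± 6.86 to 0.182 ± 0.163 CPM (-5.82 ± 0.70), with WT libraries that spread widely. Also among the 12 largest falls were CREB3L3 (-3.98 ± 0.29), ZNF618 (-3.55 ± 0.27), the glutamate transporter SLC1A3 (-3.34 ± 0.37), SLC16A9 (-2.78 ± 0.22) and CITED4 (-2.74 ± 0.46). For these 12 genes the edgeR adjusted p was 0.00540 or lower. Single libraries moved some of these falls by over 1.5 times, with log2 fold changes of -6.83 for TMPRSS15 without mutant replicate 1, -5.43 for DMXL2 without mutant replicate 2 and -2.03 for CITED4 without WT replicate 1 (-1.86 with the GC trend removed). Since the labels do not say whether counting used strand, the values of CREB5, SCN9A, HLA-B, LRRN3, IGF2BP2, DMXL2 and SLC1A3, which overlap a gene on the other strand, are less certain, as are those of HSH2D, TMPRSS15 and IGF2BP1, which overlap one on the same strand.

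**Figure D1:**
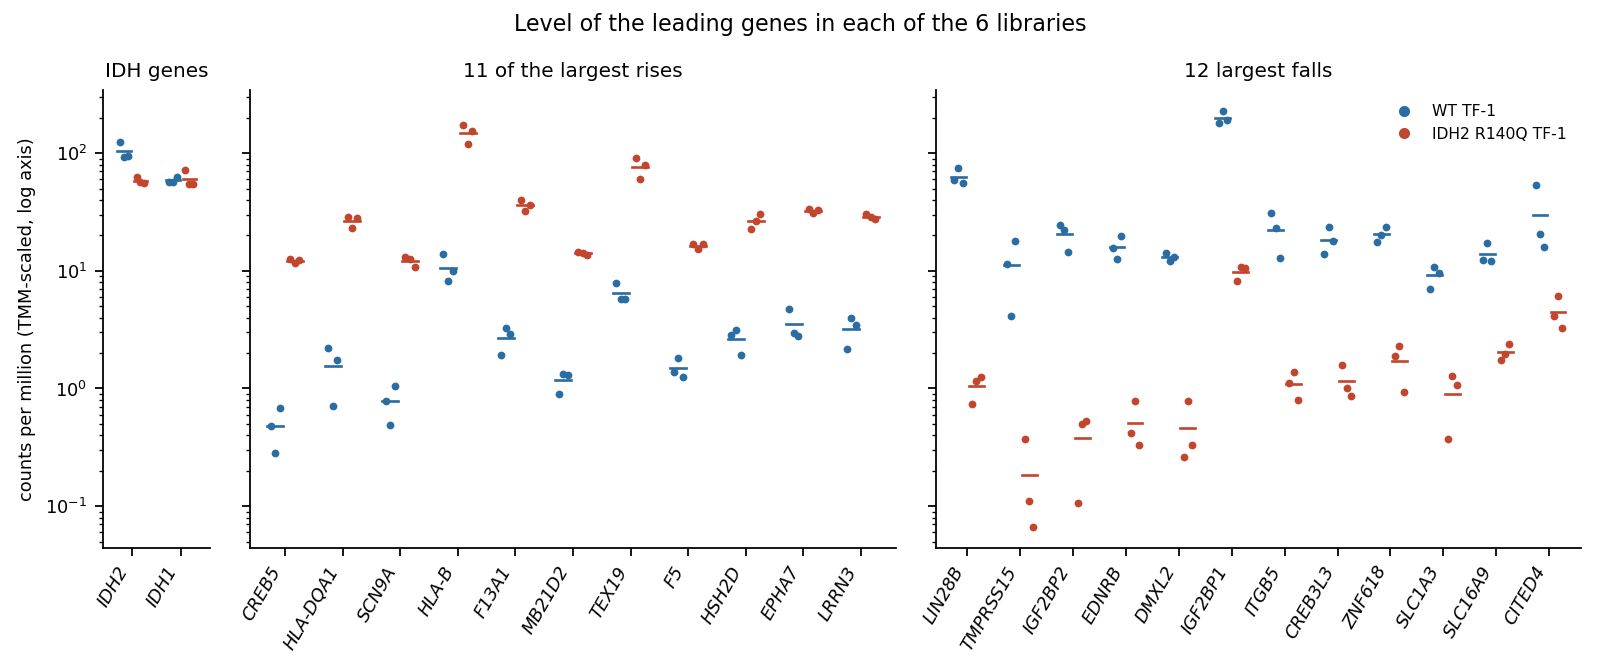
TMM-scaled CPM (log axis) of IDH2, IDH1 and 11 of the largest rises and the 12 largest falls in each of the 3 WT (blue) and 3 IDH2 R140Q (red) libraries; points are libraries and bars are group means. LIN28B sits near 63.1 CPM in WT and 1.06 CPM in mutant libraries. The groups overlap for no gene shown except IDH1, and the rule that chose the rises and falls asked for no overlap.

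Antigen presentation was the gene group that moved most. Of its 27 tested members 21 rose and 6 did not pass (24 adjusted over the list alone, camera adjusted p = 1.24e-17), with a median log2 fold change of 1.58. The call of the list was lost when the correlation between its genes was estimated (adjusted p = 0.352 with an estimated correlation), and over all 17 alternatives the adjusted p ranged from 2.43e-21 to 0.352. Class II genes rose together, among them HLA-DRA (2.37, edgeR adjusted p = 2.78e-05), HLA-DPA1 (2.52) and the invariant chain CD74 (1.90), as did CIITA (1.63), the master regulator of class II transcription. Class I genes rose as well, with HLA-C at 1.58, B2M, the shared light chain, at 0.76, the immunoproteasome subunit PSMB9 at 1.58 and the class I activator NLRC5 at 0.64. CD274, which encodes the checkpoint ligand PD-L1, rose by 1.59. PSMB10, TAPBP, HLA-E, HLA-DOB, CD80 and CD86 did not pass. Since HLA genes share reads with near-identical relatives, their single values are uncertain.

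Inflammatory and NF-kappaB genes rose as a group. Of 29 tested 17 rose and 12 did not pass (20 adjusted over the list alone, camera adjusted p = 2.41e-10), and this call held with an estimated correlation (adjusted p = 0.0461, the highest over 17 alternatives). The chemokine IL8 rose 6.30-fold (2.66 ± 0.37, edgeR adjusted p = 0.00232), and CSF2, which encodes GM-CSF, rose from 0.645 ± 0.152 to 3.55 ± 0.148 CPM (2.46 ± 0.27). Other members that rose were the interleukins IL1A (1.87) and IL1B (0.92), the apoptosis inhibitor BIRC3 (2.23), and NFKBIA (0.54) and TNFAIP3 (0.84), which restrain the pathway. RELA, the main activating subunit, was at -0.02 and did not pass (edgeR adjusted p = 0.899). Among 39 tested interferon-stimulated genes 12 rose, 1 fell and 26 did not pass (15 and 2 adjusted over the list alone, camera adjusted p = 0.00247), with IFI44 at 2.82 ± 0.36 and OASL at 2.63 ± 0.47 (3.47 and 3.38 without WT replicate 3). The interferon call was lost with fry (adjusted p = 0.157) and in the test that estimates the correlation (adjusted p = 0.816 with an estimated correlation), and over 17 alternatives the adjusted p ranged from 2.77e-05 to 0.816. The member that fell was LGALS3BP, a secreted glycoprotein, from 326 ± 24.7 to 58.4 ± 3.45 CPM (-2.48 ± 0.11, edgeR adjusted p = 1.44e-05). IFIT1 (-0.09) and IRF7 (-0.49) did not pass.

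Erythroid genes fell on balance. Of 46 tested 4 rose, 17 fell and 25 did not pass (6 and 18 adjusted over the list alone, camera adjusted p = 0.0438). The list's call was lost without WT replicate 3 (camera adjusted p = 0.319), without mutant replicate 3 (0.0615), with fry and when the correlation was estimated (adjusted p = 0.816 with an estimated correlation), with a range over 17 alternatives from 0.0103 to 0.816. The embryonic globin HBZ fell 6.43-fold (-2.68 ± 0.36, edgeR adjusted p = 0.00184), the fetal globins HBG1 and HBG2 were at -1.32 and -1.57, and the alpha globins HBA1 and HBA2 at -1.21 and -1.26. The globin chaperone AHSP (-2.05), the heme synthesis enzyme ALAS2 (-1.01), the erythropoietin receptor EPOR (-1.18 ± 0.21) and TMEM56 (-2.40 ± 0.24) also fell. Going the other way, the adult globin HBB rose from 11.6 ± 3.35 to 34.1 ± 8.21 CPM (1.55 ± 0.23, edgeR adjusted p = 0.00309) and the Rh antigen gene RHCE by 1.30 ± 0.11, and RHD and CA1 rose too. GATA1, the erythroid master regulator, was at -0.23 and did not pass (edgeR adjusted p = 0.124). EPOR and TMEM56 overlap another gene on the same strand and RHCE one on the other strand, so their values are less certain. The symbol TMEM56 is repeated in the deposited table, and the value here is that of ENSG00000152078. HBA1 and HBA2, HBG1 and HBG2, and RHCE and RHD are near-identical pairs. How reads that match both members were counted is not stated, so their single values are uncertain.

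Markers of other blood lineages moved both ways within lists, and camera called none of these lists with all libraries, the preset correlation, the filter on low counts and no GC correction. With fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, the stem and progenitor (adjusted p = 0.00355), monocyte and macrophage (0.0102) and mast cell (0.0102) lists passed. When camera estimated the correlation their adjusted p was 0.816, 0.719 and 0.571. Of 22 tested megakaryocyte genes 6 rose, 4 fell and 12 did not pass (7 and 6 adjusted over the list alone, camera adjusted p = 0.877). The integrins ITGA2 (2.02 ± 0.16) and ITGB3 (1.36 ± 0.16) rose, while the granule transport gene RAB27B (-2.24 ± 0.27) and the platelet glycoprotein GP5 (-1.67 ± 0.19) fell. Of 21 tested mast cell, basophil and eosinophil genes 9 rose, 2 fell and 10 did not pass (10 and 2 adjusted over the list alone, camera adjusted p = 0.0611). The interleukin 5 receptor IL5RA (2.56 ± 0.23) and the histamine-forming enzyme HDC (from 4.87 ± 0.996 to 27.7 ± 3.64 CPM) rose, and ALOX5 (-1.24 ± 0.25) and PTGDR2 (-0.80 ± 0.21) fell. Of 19 tested monocyte and macrophage genes 4 rose, 2 fell and 13 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 0.142). CD4 (1.45 ± 0.13) rose, and TYROBP (-1.77 ± 0.16) and CSF1R (-0.70 ± 0.18) fell. Of 18 tested neutrophil and granule genes 3 rose, 4 fell and 11 did not pass (4 and 5 adjusted over the list alone, camera adjusted p = 0.771). MS4A3 (1.55 ± 0.16) and LCN2 (1.23 ± 0.22) rose, and the granule proteins PRTN3 (-2.24 ± 0.58) and MPO (-1.06 ± 0.29) fell. PRTN3 was at -1.53 without WT replicate 1 and -2.84 without mutant replicate 1. Of 31 tested stem and progenitor genes 9 rose, 2 fell and 20 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.224). ITGA6 (1.46 ± 0.14) and CD38 (1.22 ± 0.14) rose, and the leukemia-linked genes MEIS1 (-2.40 ± 0.37) and MN1 (-2.57 ± 0.51, -1.89 without WT replicate 1) fell. Of 36 tested cytokine receptors and STAT5 targets 7 rose, 2 fell and 27 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 0.0560). IL5RA and the cytokine OSM (2.11 ± 0.16) rose, and EPOR and SPRY2 (-0.52 ± 0.10) fell. The megakaryocyte list had a median of -0.04 and a mean of -0.07 against an upward test, and the neutrophil list a median of 0.10 and a mean of -0.14 with an upward test. The mast cell list was called without mutant replicate 1 (camera adjusted p = 0.0424), WT replicate 2 (0.00737) or mutant replicate 2 (0.0319), and with all libraries but no filter on low counts (0.0120), with a range from 0.00737 to 0.571 over 17 alternatives. The cytokine list was called without WT replicate 1 (0.00699), WT replicate 2 (0.0314) or mutant replicate 2 (0.0285). With all libraries it was called with the GC trend removed (0.0110) and without a filter (0.0133), and the adjusted p had a range from 0.00699 to 0.816. Leaving out a single library raised the edgeR adjusted p above 0.05, at most to the value given, for PRTN3 and ALOX5 (0.124 and 0.0640 without mutant replicate 3), MPO, CSF1R, MN1 (0.163, 0.135, 0.0650 without mutant replicate 1) and PTGDR2 and SPRY2 (0.124 and 0.0687 without mutant replicate 2). Of the 6 fits without a single library, MPO lost its call in 6, PRTN3, CSF1R and SPRY2 in 4, and ALOX5, PTGDR2 and MN1 in 3. Other settings ended the calls of PRTN3 (limma-voom), MPO (thinned counts, the GC trend removed and DESeq2) and PTGDR2 (thinned counts).

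Few of the enzymes around the mutation changed. Of 34 tested IDH, TCA cycle and 2-hydroxyglutarate enzymes 3 fell and 31 did not pass (2 adjusted over the list alone, camera adjusted p = 0.557). IDH2, IDH3B (-0.54 ± 0.11) and BCAT1 (-0.41), a branched-chain transaminase that consumes 2-oxoglutarate, were the members that fell. Of 44 tested DNA and histone methylation regulators, among them demethylases that use 2-oxoglutarate, 1 rose, 3 fell and 40 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.452). The DNA methyltransferase DNMT3B fell 1.95-fold (-0.96 ± 0.11, edgeR adjusted p = 0.000918), UHRF1, which directs maintenance methylation, was at -0.61 ± 0.11, ASXL1 was at -0.61, and the histone demethylase KDM4C rose by 0.51 ± 0.14. IDH3B, DNMT3B and ASXL1 lie on chromosome 20, where 192 of 398 tested genes fell. Of 31 tested glycolysis and pentose phosphate enzymes 3 fell and 28 did not pass (3 adjusted over the list alone, camera adjusted p = 0.201). The hexokinase HK1 fell from 1349 ± 119 to 689.8 ± 45.5 CPM (-0.97 ± 0.12). Of 52 tested nuclear-encoded subunits of oxidative phosphorylation 2 fell and 50 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.940). ATP5D (-0.52 ± 0.13) and COX6B1 (-0.45 ± 0.12) fell. The list had a median of 0.01 and a mean of 0.01 against a downward test. By edgeR, DESeq2 or limma-voom 0 of 13 mitochondrially encoded genes changed, 0 adjusted over the list alone and 0 at an unadjusted p below 0.05 (camera adjusted p = 0.663). MT-CO1 was at -0.36 ± 0.24 and MT-ND4 at -0.38 ± 0.33 (0.11 without WT replicate 1). Without WT replicate 1 the glycolysis and oxidative phosphorylation lists were called lower (camera adjusted p = 0.0380 and 0.0423), and without WT replicate 2 the mitochondrially encoded list was (0.0330). Over 17 alternatives these ranged from 0.0380 to 0.816, from 0.0423 to 0.985 and from 0.0330 to 0.983. Calls lost without a single library, with the highest edgeR adjusted p, were those of IDH3B, UHRF1, KDM4C (0.0766, 0.0502, 0.165 without mutant replicate 1) and ATP5D and COX6B1 (0.125 and 0.160 without mutant replicate 3). Of the 6 such fits COX6B1 lost its call in 5, KDM4C and ATP5D in 4, IDH3B in 3 and UHRF1 in 1. Another setting also ended the calls of KDM4C (the GC trend removed), ATP5D (the GC trend removed) and COX6B1 (library size alone and the GC trend removed).

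Most tested members of the hypoxia, ATF4, lipid and NRF2 lists did not pass, as was so for all tested genes, of which 2188 of 15389 changed. Of 30 tested hypoxia and HIF targets 5 rose, 2 fell and 23 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.201). VEGFA (from 74.4 ± 39.6 to 177 ± 25.5 CPM) and NDRG1 (1.15 ± 0.15) rose, and the prolyl hydroxylase EGLN3 (-0.78 ± 0.19) and PFKFB4 (-0.63 ± 0.11) fell. Of 34 tested serine synthesis and ATF4 genes 3 rose and 31 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0699). The stress factor ATF3 (2.72 ± 0.62, 3.59 without WT replicate 1 and 2.11 without mutant replicate 1) and the amino acid transporter SLC1A4 (0.82 ± 0.14) rose. Of 26 tested cholesterol synthesis genes 3 rose, 2 fell and 21 did not pass (3 and 3 adjusted over the list alone, camera adjusted p = 0.819). STARD4 (0.90 ± 0.21) and IDI1 (0.38 ± 0.10) rose, and CYP51A1 (-1.16 ± 0.30) and TM7SF2 (-0.53 ± 0.15) fell. The list had a median of 0.01, a mean of -0.01 and an upward test. Of 44 tested fatty acid and sphingolipid genes 6 rose, 2 fell and 36 did not pass (7 and 4 adjusted over the list alone, camera adjusted p = 0.505). SGMS2 (1.44 ± 0.22) and the elongase ELOVL7 (1.10 ± 0.12) rose, and the desaturases SCD (-0.47 ± 0.11) and FADS2 (-0.45 ± 0.10) fell. Of 34 tested NRF2 and iron genes 6 fell and 28 did not pass (6 adjusted over the list alone, camera adjusted p = 0.348). The sulfiredoxin SRXN1 (-1.63 ± 0.46, -0.88 without WT replicate 1), which lies on chromosome 20, was among those that fell. The ATF4 list was called without WT replicate 1 (camera adjusted p = 0.00771) or mutant replicate 2 (0.00678). With all libraries it was called with the GC trend removed (0.0110) and without a filter (0.0197), and the adjusted p had a range from 0.00678 to 0.848 over 17 alternatives. Single libraries also ended calls here, with edgeR adjusted p up to the value given, for VEGFA, PFKFB4, ATF3, STARD4, CYP51A1, SRXN1 (0.127, 0.0510, 0.0947, 0.107, 0.136, 0.185 without mutant replicate 1), EGLN3, IDI1, TM7SF2, SCD (0.111, 0.150, 0.157, 0.127 without mutant replicate 3) and FADS2 (0.112 without mutant replicate 2). Of the 6 such fits CYP51A1 lost its call in 5 and VEGFA, SRXN1, EGLN3, IDI1, TM7SF2 and FADS2 in 4. ATF3, STARD4 and SCD lost theirs in 3 and PFKFB4 in 1. Calls also ended under other settings for IDI1 (no filter and the GC trend removed), CYP51A1 (thinned counts and DESeq2), TM7SF2 (library size alone, the GC trend removed and limma-voom), FADS2 (the GC trend removed) and SRXN1 (limma-voom).

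Among survival genes BCL2, BCL2A1 and BCL2L1 rose, while most proliferation genes did not pass. BCL2 rose 4.09-fold, from 2.97 ± 0.292 to 12.2 ± 1.17 CPM (2.03 ± 0.17, edgeR adjusted p = 0.000201), BCL2A1 was at 2.15 ± 0.48 (3.05 without WT replicate 1) and BCL2L1, which encodes BCL-XL, at 1.28, while the pro-apoptotic BOK fell (-0.87 ± 0.24). BCL2 overlaps another gene on the same strand, which makes its value less certain. Of 16 tested family members 3 rose, 1 fell and 12 did not pass (3 and 3 adjusted over the list alone, camera adjusted p = 0.219). With fry this list passed (adjusted p = 0.0232), with a range from 0.0232 to 0.816 over 17 alternatives. Of 45 tested cell cycle and mitosis genes 1 rose, 6 fell and 38 did not pass (1 and 7 adjusted over the list alone, camera adjusted p = 0.142). The spindle factor TPX2 rose (0.95 ± 0.16) and E2F1 (-1.27 ± 0.22) and UBE2C (-1.03 ± 0.12) fell, and like BCL2L1 all lie on chromosome 20. Of 34 tested MYC target and ribosome biogenesis genes 1 fell and 33 did not pass (1 adjusted over the list alone, camera adjusted p = 0.365). The chaperone HSPD1 fell from 781 ± 191 to 362 ± 9.13 CPM (-1.11 ± 0.18). Without WT replicate 1 the cell cycle and MYC lists were called lower (camera adjusted p = 0.000192 and 0.00143), with ranges over 17 alternatives from 0.000192 to 0.898 and from 0.00143 to 0.964. Of 24 tested p53 targets 2 rose and 22 did not pass (2 adjusted over the list alone, camera adjusted p = 0.663). The cell cycle inhibitor CDKN1A (1.38 ± 0.20) and the death receptor FAS (1.01 ± 0.23) rose, and the list had a median of -0.07, a mean of 0.06 and an upward test. Of 29 tested immediate-early and heat shock genes 2 rose and 27 did not pass (1 adjusted over the list alone, camera adjusted p = 0.846). ATF3 and FOS (1.01 ± 0.27) rose. Calls that did not survive the loss of a library, with the highest edgeR adjusted p, were those of BCL2A1 and FAS (0.0909 and 0.106 without mutant replicate 1), BOK (0.143 without mutant replicate 3) and FOS (0.120 without mutant replicate 2), and another setting ended those of BOK (limma-voom) and FOS (thinned counts and DESeq2). Of the 6 such fits FAS, BOK and FOS lost their calls in 4 and BCL2A1 in 3.

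Of 35 tested TGF-beta, adhesion and matrix genes 5 rose, 6 fell and 24 did not pass (9 and 7 adjusted over the list alone, camera adjusted p = 0.365). The collagen COL5A1 (3.76 ± 0.32) and caveolin CAV1 (2.43 ± 0.18) rose, and ITGB5 and COL6A1 (-1.43 ± 0.28) fell. Of 11 tested cancer-testis genes, normally limited to the germ line, 5 rose, 1 fell and 5 did not pass (5 and 2 adjusted over the list alone, camera adjusted p = 0.0699). MAGEC1 rose from 6.76 ± 4.03 to 54.1 ± 4.01 CPM, by over 1.5 times more without WT replicate 3 (log2 fold change 3.61), and MAGEB2 by 3.24 ± 0.50, whereas PRAME fell (-0.82 ± 0.14), and reads may be shared between close relatives among the MAGE genes. This list was called without WT replicate 3 (camera adjusted p = 0.0111) and without a filter (0.0197), with a range from 0.0111 to 0.816 over 17 alternatives. Among markers of cells that a TF-1 culture should not hold, of 10 tested lymphocyte genes 2 rose, 5 fell and 3 did not pass (3 and 5 adjusted over the list alone, camera adjusted p = 0.452). Of 17 tested epithelial, endothelial and fibroblast genes 1 rose, 1 fell and 15 did not pass (1 and 1 adjusted over the list alone, camera adjusted p = 0.666). Cytotoxic granule genes GNLY (1.61 ± 0.17) and PRF1 (1.10 ± 0.29) were higher and CD22 (-1.87 ± 0.12) and CD7 (-1.70 ± 0.31) lower, and ESAM (0.41 ± 0.09) was higher and CDH5 (-1.56 ± 0.22) lower. Without single libraries the edgeR adjusted p rose above 0.05, at most to the value given, for COL6A1 and ESAM (0.0568 and 0.105 without mutant replicate 3) and PRF1 (0.160 without mutant replicate 1). Of the 6 such fits ESAM lost its call in 4, PRF1 in 3 and COL6A1 in 2.

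**Figure D2:**
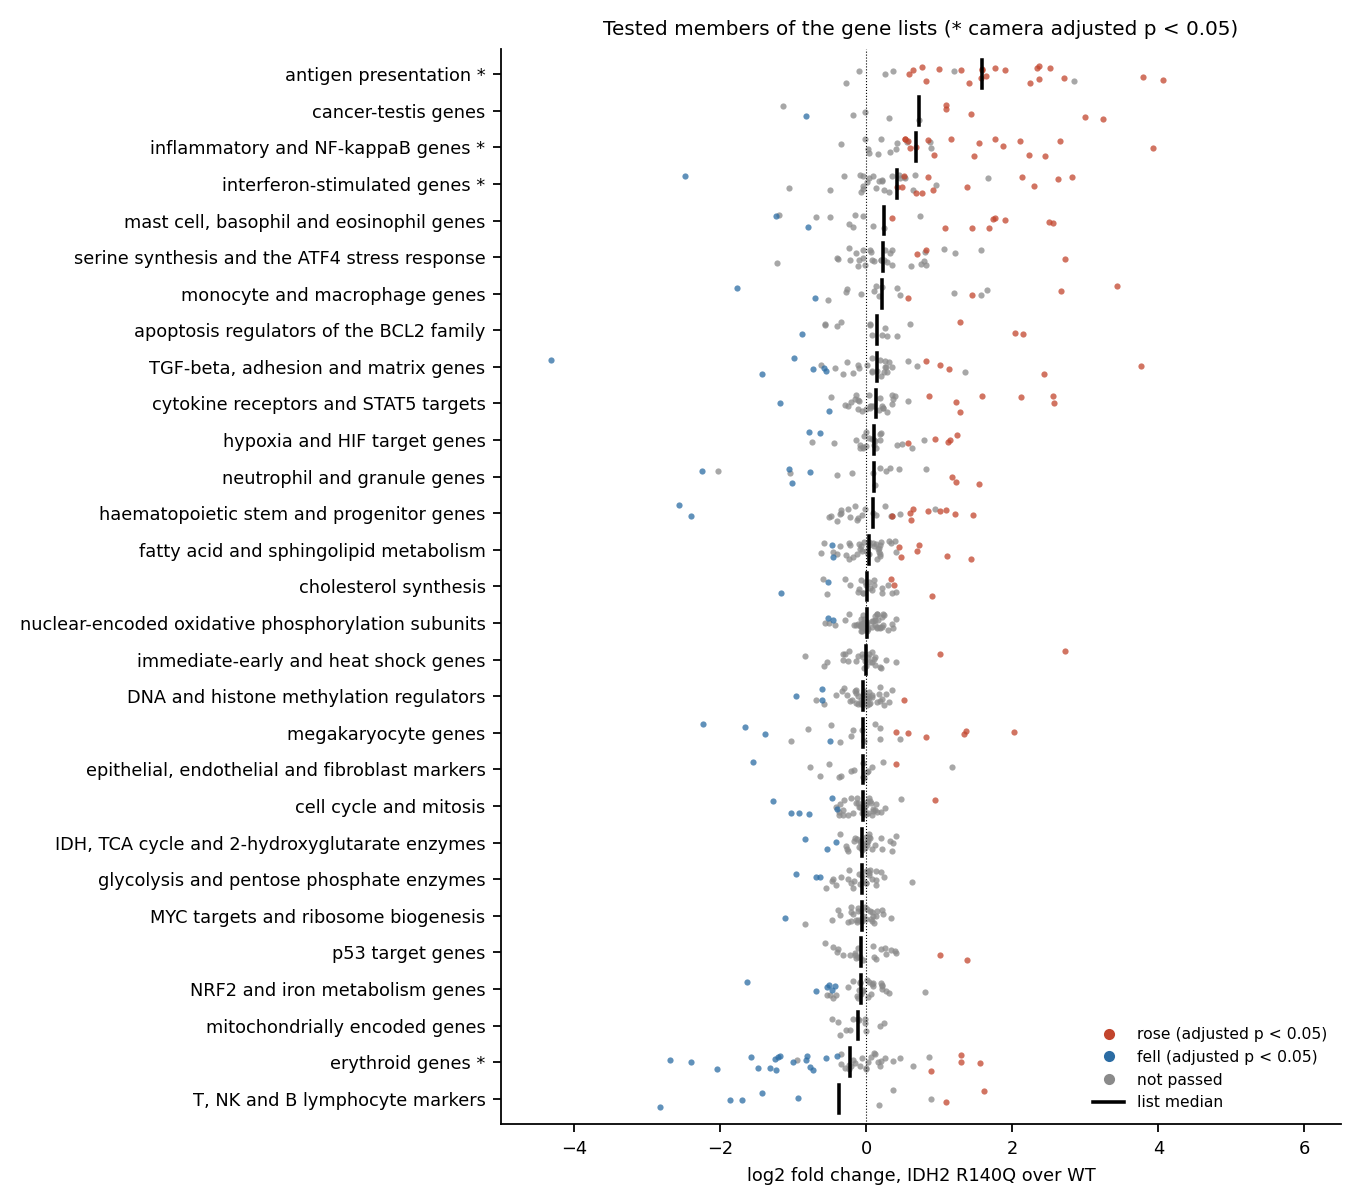
Log2 fold change (mutant over WT, horizontal axis) of the tested members of the 29 gene lists, ordered by list median (black bar); red points rose, blue points fell and grey points did not pass. Antigen presentation has the highest median, 1.58, and 21 of its 27 members lie among the red points.

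Chromosome 20 stood apart when genes were grouped by position. Of its 398 tested genes 192 fell and 11 rose, with a median log2 fold change of -0.56 (95% bootstrap interval -0.62 to -0.51, camera adjusted p = 3.83e-23), and the call held with an estimated correlation (adjusted p = 0.00249). The median difference from the WT mean was -0.53, -0.53 and -0.51 in mutant replicates 1, 2 and 3. In 10 Mb windows the median was -0.40 at the start of the chromosome, -0.20 from 10 to 20 Mb and 0.09 from 20 to 30 Mb. It lay between -0.60 and -0.81 in each of the windows beyond 30 Mb. With the preset correlation camera also called chromosomes 4, 8, 13 and 14 higher and 16 and 19 lower, with medians from -0.23 to 0.15, and none of these held with an estimated correlation (adjusted p = 0.339 or higher). Removing the GC trend of each library left the calls of chromosomes 14, 16 and 20, and leaving out WT replicate 1 those of 8, 14, 16 and 20.

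**Figure D3:**
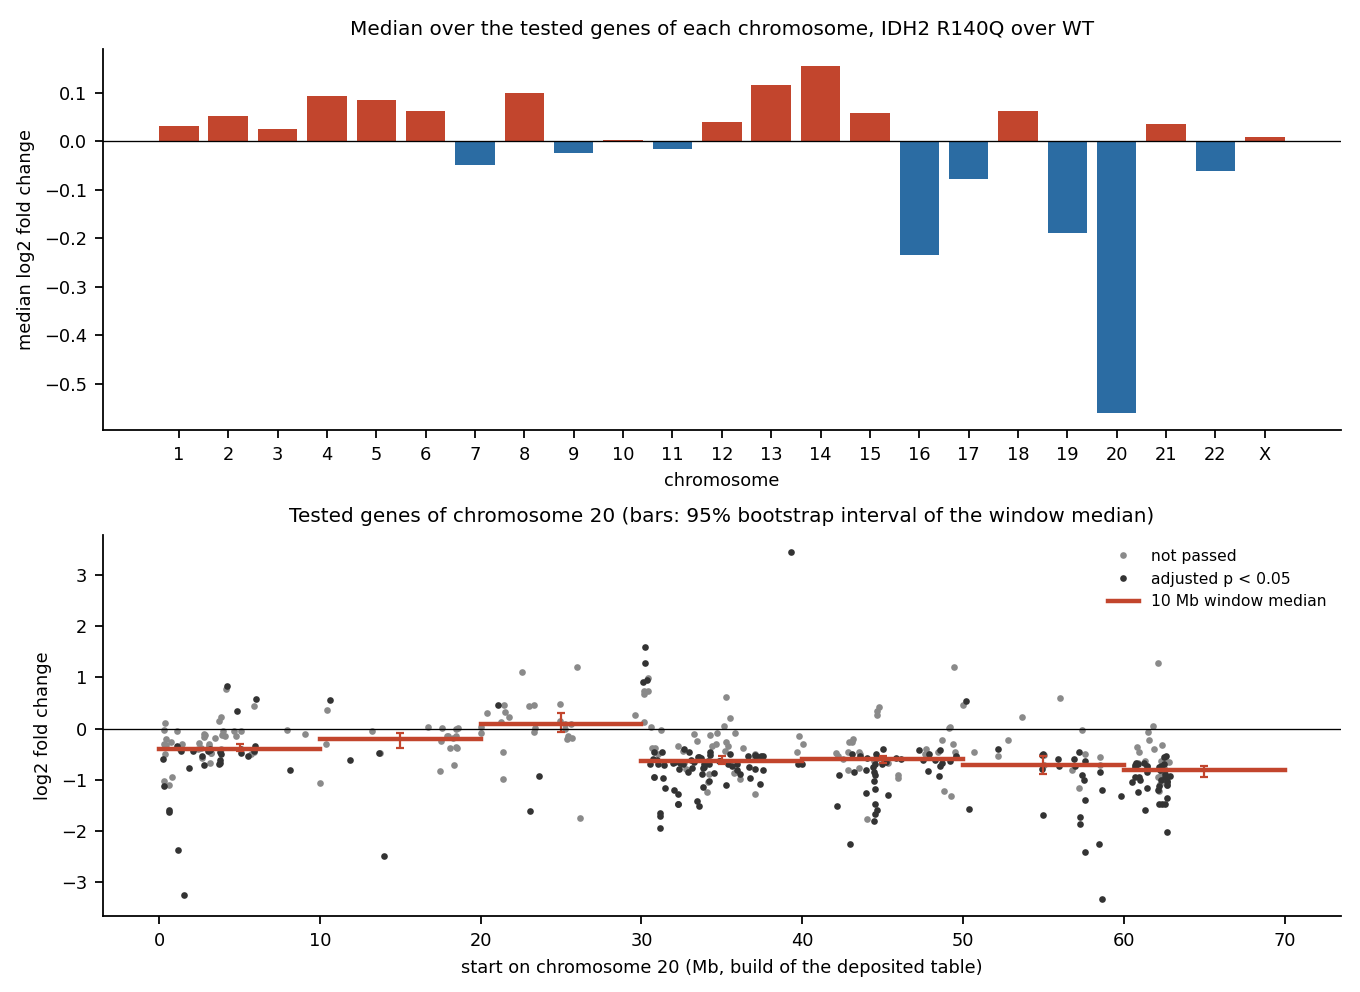
Top, median log2 fold change (mutant over WT) of the tested genes of each chromosome; bottom, log2 fold change of each tested gene of chromosome 20 against its start (Mb), with 10 Mb window medians (red lines) and 95% bootstrap intervals (red bars). Chromosome 20 has the lowest median, -0.56, and the window from 20 to 30 Mb lies at 0.09.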

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

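The tests with the GC trend of each library removed and with chromosome 20 left out were chosen after the data were seen, and the other alternatives before. Of the 104 named genes, 71 kept their direction and their side of the threshold under each of up to 16 alternatives, and of 1663 comparisons 129 lost a call and 3 turned direction. Of the 29 lists, 10 kept both under each of 17 alternatives, and of 493 comparisons 7 lost a call, 24 gained one and 14 turned direction. No paired analysis was run, because the labels pair no WT library with a mutant one. The replicate numbers used here only follow the order of the samples.

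Genes changed numbered 3441 without a filter, where 29323 genes were tested, and 901 at an adjusted p under 0.01. With single libraries left out they ranged from 897 to 3814. Higher genes numbered 527 at the stricter threshold and ranged from 527 to 2017 without single libraries. Lower genes numbered 1830 without a filter and 374 at the stricter threshold, with a range from 370 to 1797. Genes changed at least 2-fold numbered 543 at the stricter threshold and ranged from 554 to 1162. Lists called numbered 8 without a filter and 1 when camera estimated the correlation, and ranged from 3 to 10 without single libraries. Chromosomes called numbered 1 with the estimated correlation and 3 with the GC trend removed, and ranged from 4 to 8 without single libraries. The stricter threshold lowers a count by construction, and for the others the cause was not tested.

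With the GC trend removed IDH1 had a log2 fold change of -0.0866, and it ranged from -0.11 to 0.11 without single libraries. MT-ND4 ranged from -0.67 to 0.11. Oxidative phosphorylation turned direction with library size alone (adjusted p = 0.937) and without a filter (0.705), and the epithelial, endothelial and fibroblast list with the GC trend removed (0.583). Some lists turned direction without a single library, with these ranges of adjusted p over the 6 fits. Megakaryocyte genes lay between 0.700 and 0.993, oxidative phosphorylation between 0.0423 and 0.974, mitochondrially encoded genes between 0.0330 and 0.983, and cholesterol synthesis between 0.581 and 0.983. MYC targets lay between 0.00143 and 0.964, immediate-early genes between 0.599 and 0.957, and the epithelial, endothelial and fibroblast list between 0.319 and 0.765. The cause was not tested.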

Other observations

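Tests of the spread of fold changes on chromosome 20 from PDRG1 on, of B cell and monocyte levels against the rise of HLA-DRA, of the bootstrap interval of the window from 20 to 30 Mb, of other splits of the libraries and of let-7 sites under other matchings were chosen after the results were seen. A run of neighbours on chromosome 20, just before PDRG1, was higher in the mutant line although most of the chromosome was lower. From 30102231 to 30458550, HM13 (log2 fold change 0.90 ± 0.13, edgeR adjusted p = 0.00250), ID1 (1.58 ± 0.16, 0.000518), BCL2L1 (1.28 ± 0.12, 0.000382) and TPX2 (0.95 ± 0.16, 0.00563) rose. The other protein-coding genes of the run, MYLK2 (0.74) and DUSP15 (0.99), did not pass. The ends of the run were set from these values, so a comparison with other runs of that length would test nothing. BCL2L1 encodes the survival protein BCL-XL, and ID1 inhibits differentiation factors of the helix-loop-helix class.

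The following single genes were chosen after their values were seen and stand for no group. ARID3A (-1.35, edgeR adjusted p = 0.000716), ARID3B (-0.80, 0.00169), TRIM71 (-1.32, 0.00921) and HMGA1 (-0.60, 0.0130) fell, whereas BCL11A, a repressor of fetal globin, rose (1.09, 0.00274). IGF2BP3 was at -0.26 and did not pass (0.172). On the long arm of chromosome 16, the windows from 60 to 70 and 70 to 80 Mb had median log2 fold changes of -0.45 and -0.46.

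Chromosome 20 genes were lower in the mutant line, and the tables argue against GC bias and against WT replicate 1 alone as the cause, since the median stayed at -0.53 with the GC trend removed and at -0.58 without that library. An even shift of the whole chromosome is argued against by the window from 20 to 30 Mb, where 27 genes had a median of 0.0888 (95% bootstrap interval -0.07 to 0.31). The bound set beforehand, at least 1 in 4 windows above -0.1, was not met, since 1 of 7 was. That window lies next to the higher run. On its own it cannot exclude fewer copies of the whole chromosome together with a local change there. But the first window and that from 10 to 20 Mb, away from the run, had medians of -0.40 (-0.45 to -0.31) and -0.20 (-0.38 to -0.09). With the GC trend removed both were at -0.30. Both lie above the part from PDRG1 on, which argues against an equal loss along the whole chromosome with a change only near the run. From PDRG1 to the end, 93.6% of 267 genes lay below 0, with a median of -0.68 (-0.71 to -0.64), and among genes with a mean CPM of at least 10 the spread there was 0.939 times that on other autosomes, as one shift of all genes would give. Fewer copies of that part in the mutant line may be a candidate explanation. For 2 copies in place of 3 the value would be -0.58 in log2, which lies outside that interval. But the interval resamples genes only, and the start at PDRG1 was set from these values. Of the windows beyond 30 Mb, the last had an interval below -0.58 (-0.94 to -0.72) and those of the others held it. With the GC trend removed the median of the last window was -0.62, and the windows beyond 30 Mb ranged from -0.59 to -0.74. No intervals were computed for these values. The number of copies therefore stays open. DNA was not measured, copy changes between lines kept apart and effects of the mutation remain open, and 122 genes before 30 Mb had a median of -0.29 (-0.38 to -0.15), which was not explained.

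HLA and antigen presentation genes were higher in the mutant line. A gain of the HLA region is argued against by its 120 other tested coding genes from 28 to 34 Mb of chromosome 6, with a median of -0.0536. Among B cell and monocyte genes, MS4A1, CD14, FCN1 and S100A9 reached a mean of at most 0.141 CPM in the mutant line. That was 0.0511% of the rise of HLA-DRA by 275 CPM. They were picked from 8 such genes after the values were seen, so they argue only against cells that express them. Of the 8 genes 4 passed the filter and 0 of these were called higher by edgeR. CD79B came nearest, at a log2 fold change of 0.89 with an edgeR adjusted p of 0.0678. The summed level of the 8 in the mutant line was 59.4 CPM against 341 CPM for HLA-DRA, which did not meet the bound set beforehand. LYZ was as high in WT libraries, so these values leave cells of another type in the mutant cultures open. Other cells such as dendritic cells could still contribute. A response of the mutant cells themselves, or of cells kept longer in culture, may explain the rise, and the labels give no sample to tell these apart.

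LIN28B, IGF2BP1 and IGF2BP2 were lower in the mutant line, and LIN28B restrains let-7, so that more let-7 activity was tested as a hypothesis. The 540 genes with a let-7 8-mer site in the 3′ UTR had a median log2 fold change 0.07 below matched genes among 11959 without one, and 0.716% of 419 control 8-mers gave a difference as low. Those controls were reorderings of the bases of the let-7 site. Some of them hold a shorter let-7 match, so the controls were not free of let-7 sites. The median of the site genes themselves was -0.01, as was that of all tested genes, so that they were lower only against matched genes. The difference of site genes from matched genes was -0.06 when genes were also matched on UTR GC. It was -0.07 with the GC trend removed and -0.07 without WT replicate 1. More let-7 activity may accompany the fall of LIN28B, with a small effect, but microRNAs were not measured, 252 coding genes had no usable 3′ UTR, and whether it lowers IGF2BP1 and IGF2BP2 was not tested.

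The 6 libraries can be split into groups of 3 in 10 ways, and 1 split, the real one, gave 2188 genes, against at most 0 in the others. With 10 splits a share under 0.05 cannot be reached. Each of the other splits puts libraries of both lines in each group, which widens the spread within groups. Their 0 calls therefore give no measure of chance.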
